A study of Mus musculus with 2 samples.

How the data were processed

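Total RNA from undifferentiated PGK12.1 cells, a female mouse embryonic stem cell line, and from the same line after 15 days of differentiation as embryoid bodies was hybridised to Affymetrix mouse expression arrays, 1 array per condition. Per the labels' protocols, stem cells were grown with leukemia inhibitory factor on fibroblast feeders, feeders were removed by adhesion to gelatin before collection or differentiation, RNA was purified on columns with a DNase step, and biotinylated cRNA was made by the manufacturer's protocol. The deposited values are linear signal intensity, 1 number per probe set and array, for 45101 probe sets. The software that summarised the probes was not given in the sources used here. The mean signal after trimming 2% of probe sets from each tail was 250 on both arrays, so the deposited intensity values had already been scaled to a common level. The median signal was 35.1 on the undifferentiated array and 39.0 on the day 15 array. No detection calls came with the values.

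The 64 Affymetrix control probe sets were set aside, which left 45037. Probe sets were named through the platform annotation: 34945 of them named 1 gene, 932 named several genes and were not used for gene values, and 9160 were not listed there. Symbols were brought up to date and chromosomes assigned through the RefSeq gene table of assembly GRCm38.p6, by gene identifier for 34741 probe sets and by symbol for 143, while 61 stayed unplaced. The array files name no genome build, so no coordinates are printed. Signals were taken to log2(signal + 16), and the log2 difference of a gene is its log2 value at day 15 minus that in undifferentiated cells. The pseudocount of 16 damps the differences of dim genes, so these values understate their size, and folds in the text are ratios of the signals themselves. A gene was represented by the probe set with the highest mean log2 value over both arrays, and 18193 genes were measured. The 11960 genes whose mean was at or above the median of all probe sets, equal to a signal of about 36.5, entered the counts and medians, of which 418 were X-linked and 11524 autosomal.

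With 1 array per condition there is no replicate error, no test between conditions and no p-value. Genes were therefore called by size, as at least 2-fold higher or lower. Among the 5157 genes with more than 1 probe set above the filter, probe sets of the same gene differed in their log2 difference with an SD of 0.53, and 1559 of these genes had probe sets of opposite direction. The log2 ratio of day 15 over undifferentiated of the 18 hybridization control probe sets had an SD of 0.11, which covers hybridization alone. Neither SD includes variation between cultures. The 15 bacterial Phe, Thr and Trpn control probe sets, for which no target RNA was seen on either array, reached at most 35.6. Where the dimmer array lay below 35.6, the fold is given as at least the brighter signal over 35.6, and where both lay below it no fold is given. This bound was chosen after the data were seen.

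A gene group was placed by the percentile of its median log2 difference among 10000 random lists of equal size, matched on mean expression in 20 bins. Lists for the X and for each autosome were drawn from other autosomal genes. These percentiles describe this pair of arrays, since genes are not replicates and neighbouring or co-regulated genes do not vary independently. Intervals of a median over genes are 95% intervals from binomial order statistics, and intervals of a share of genes are exact 95% binomial (Clopper-Pearson) intervals. The 32 gene lists, the filter, the pseudocount, the size threshold and the rule for the named genes were fixed before the data were examined. That rule took the 12 genes with the largest positive and the 12 with the largest negative log2 difference among genes whose probe sets above the filter all had the same direction, 8 X-linked genes on each side by the same rule, up to 4 members of each list with the largest absolute difference, and all measured genes of the X-inactivation centre and escape lists. Pou5f1, Nanog, Sox2, Dppa5a, Klf4, Thy1 and the other genes named outside this rule were chosen after their values were seen.

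In simulated data 200 genes were changed and 11961 were tested, with a noise SD of 0.3. All genes changed 8-fold, all genes raised 4-fold and 98% of those lowered 4-fold were called, against 0.0935% of the other genes. With a noise SD of 0.53, the spread measured between probe sets of 1 gene, 4.30% of the other genes were called. In each group of changed genes at least 95.9% were called. The lower rate therefore does not hold for these arrays. Both rates include the X-linked genes, which the simulation shifted by -0.30. A simulated X-linked shift of -0.30 was recovered as -0.26 with the SD of 0.3 and as -0.25 with that of 0.53. The alternatives were no expression filter, a filter at the 75th percentile, the mean over probe sets, leaving out probe sets with the suffix a, s or x, centring on the median, quantile normalization, pseudocounts of 1 and 64, and size thresholds of 1.5-fold and 4-fold. For the X-linked difference they also were means, genes past 2-fold left out, the X-linked lists left out and each autosome left out in turn. Scaling on the hybridization controls, a filter on the control bound, the first X window left out and matching on gene span were added after the data were seen. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.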

Results

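Expression was compared between undifferentiated PGK12.1 cells, a female mouse embryonic stem cell line, and cells of the same line after 15 days of embryoid body differentiation, with 1 array for each. The stated aim was to follow expression of the X chromosome as the cells pass from 2 active X chromosomes to a single active X. Signals on the undifferentiated array ran from 0.1 to 17939 and on the day 15 array from 0 to 17574. The number of arrays limits the precision: no value below has a replicate error, and a difference is described by its size alone.

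Collagens and other matrix genes had the largest gains at day 15, and germ line and stem cell genes were among the largest losses. Of 11960 genes above the expression filter, 1975 (16.5%) were at least 2-fold higher at day 15 and 1006 (8.41%) at least 2-fold lower. Folds are ratios of signals, given as at least N-fold where the dimmer signal lay below the bacterial controls without target (35.6), and calls of 2-fold use log2(signal + 16). The highest gains were of Col1a1, a chain of type I collagen, at a signal of 17.2 in undifferentiated cells and 7728 at day 15 (at least 217-fold), and of Col3a1, the type III collagen chain, at 39.0 and 10400 (267-fold). They were followed by the semaphorin and VEGF co-receptor Nrp1 (at least 146-fold), the serine protease Prss23 (188-fold), the mesenchymal cadherin Cdh11 (at least 152-fold), the X-linked basement membrane collagen Col4a5 (at least 80.2-fold) and the matrix proteoglycan Lum (at least 74.7-fold). The imprinted gene Dlk1 (107-fold), the matrix protein gene Postn (at least 104-fold), Col8a1 (at least 48.8-fold), the transcription factor Snai2 (at least 82.1-fold) and the muscle gene Ankrd1 (at least 69.0-fold) completed the 12.

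Losses were smaller in size. The X-linked gene Glod5 was lower at day 15 by at least 15.6-fold (signals 554 and 25.3), the epidermal transglutaminase Tgm1 by 14.9-fold, the zona pellucida gene Zp3 by 9.77-fold and the guanine nucleotide exchange factor Rasgrp2 by 8.33-fold. Tdrd12, a Tudor domain gene of the piRNA pathway, was 7.72-fold lower, Pramel7 at least 7.61-fold, Dppa3 7.22-fold, Aoah at least 6.78-fold and the interferon-induced transmembrane gene Ifitm1 6.65-fold. Slc38a5, an X-linked amino acid transporter gene, was at least 5.38-fold lower, Sned1 at least 5.21-fold and Gpr4 at least 3.81-fold. The genes at least 2-fold lower at day 15 held 68 past 4-fold, and the genes at least 2-fold higher at day 15 held 782.

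The balance between higher and lower genes depended on how the arrays were scaled. As deposited, 66.3% of the genes past 2-fold were higher at day 15. Quantile normalization, which moved the median gene by -0.13 on the log2 scale, gave 54.6%, and scaling on the bacterial hybridization controls, which moved it by -0.39, gave 35.7%. With that second scaling the genes at least 2-fold lower at day 15 numbered 2397. All differences below are on the deposited scaling. Scaling on those controls turns each positive log2 difference, list median or list mean under 0.39 to below 0.

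Pluripotency transcripts were lower at day 15 as a group. Of 27 measured pluripotency factors, 17 were at least 2-fold lower, 10 lay between and 0 were at least 2-fold higher, with a median log2 difference of -1.13, below all 10000 matched random lists. Dppa3 had the largest loss (1101 and 153), then the TGF-beta family ligand Gdf3 (4.61-fold lower), the RNA-binding protein gene Lin28a (4.37-fold) and Sall4 (3.51-fold). Pou5f1, which encodes OCT4, still measured 2932 at day 15 against 7838 before, Nanog 2835 against 5470 and Sox2 3729 against 6138. Dppa5a (14474 and 11467) and Klf4 (3267 and 2859) differed by less than 1.3-fold. Of 8 primed epiblast markers 4 were at least 2-fold lower and 0 higher (median -0.92, percentile 0.1, but 3.40 with probe sets of suffix a, s or x left out), led by the de novo DNA methyltransferase gene Dnmt3b (3.68-fold lower), Foxd3 (2.58-fold), Otx2 (2.42-fold) and Pou3f1 (2.23-fold). The 15 germ line and cleavage-stage markers had a median of -0.52 (percentile 0.42, but 7.95 with the filter at the 75th percentile), with 5 at least 2-fold lower, among them Dppa3, the meiotic gene Hormad1 (3.16-fold) and Tex19.1 (2.75-fold), and 2 higher, of which Tdrd7 was at least 5.18-fold higher.

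Genes of DNA methylation and proliferation genes were lower as groups, while cyclin-dependent kinase inhibitors, D cyclins and retinoblastoma family genes were higher. Among 10 DNA methylation and demethylation genes 4 were at least 2-fold lower and 1 higher (median -0.93, percentile 0.05, but -0.53 and percentile 8.35 with the mean over probe sets): Dnmt3l was 4.54-fold lower, Dnmt3b 3.68-fold, the methylcytosine oxidase gene Tet1 3.01-fold, with 1 dim probe set above the filter in the opposite direction, and Uhrf1, which recruits the maintenance methyltransferase, 2.83-fold. Among 23 proliferation genes 9 were at least 2-fold lower and 0 higher (median -0.86, below all matched lists), led by cyclin E gene Ccne1 (3.77-fold lower), Mybl2 (2.81-fold) and the replicative helicase genes Mcm2 (2.78-fold) and Mcm3 (2.60-fold). Of 13 cyclin-dependent kinase inhibitors, D cyclins and retinoblastoma family genes, 7 were at least 2-fold higher and 0 lower (median 1.19, percentile 99.95). Ccnd2 was 21.3-fold higher, Cdkn2b 16.5-fold, Cdkn1a 12.9-fold and Cdkn1b 4.31-fold.

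Fibroblast and matrix genes formed the group with the largest gain. Of 22 such genes, 21 were at least 2-fold higher at day 15 (median 4.59, above all matched lists), including Col1a1, Col3a1, Lum and Postn. Thy1 was the exception, with signals of 143.5 and 144.5 (the list holds genes that feeder fibroblasts also make). Of 6 smooth muscle markers 5 were at least 2-fold higher (median 4.42, above all matched lists): Actg2 by at least 43.3-fold, Tagln by 28.3-fold, Acta2 by 24.7-fold and Cald1 by 19.7-fold. Of the 8 measured members, Myh11 (log2 difference 0.27) and Myocd (-0.23) lay below the filter, and Smtn, above it, was at 0.28. Visceral and primitive endoderm markers were at least 2-fold higher for 10 of 16 and lower for 0 (median 2.09, above all matched lists). Afp, the fetal serum protein of yolk sac and liver, was higher by at least 24.4-fold, the transthyretin gene Ttr by at least 15.9-fold, and the basement membrane collagens Col4a1 and Col4a2 by 38.2-fold and 38.1-fold. Of 17 cardiac muscle markers 7 were at least 2-fold higher and 0 lower (median 0.88, percentile 99.2). They were led by cardiac troponin T gene Tnnt2 (at least 34.5-fold), Hand2 (18.0 and 1779), Tbx20 (at least 23.6-fold) and Actc1 (7.58-fold). Another Tbx20 probe set above the filter read 33.5 and 63.7. The cardiac members within 2-fold included Nkx2-5 (log2 difference 0.44), Myh6 (0.31), Myh7 (0.59) and Myl2 (0.45).

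Other lineages were represented unevenly. Neural markers had a median of -0.52 (percentile 0.58), and of 14 genes 4 were at least 2-fold lower, with Neurod1 at 3.47-fold and Nefl at 2.79-fold, and 3 at least 2-fold higher, among them Ncam1 (10.3-fold) and Sox1 (2.89-fold). The neural list lay inside its matched range without a filter (-0.25, percentile 7.45), with the filter at the 75th percentile (-0.15, percentile 36.9) and with quantile normalization (-0.56, percentile 3.80). Hox genes had a median of 0.90 (percentile 99.1), with 6 of 13 at least 2-fold higher and 1 lower. Hoxb3 was higher by at least 4.60-fold, Hoxb2 by 5.41-fold, Hoxa11 by 4.81-fold and Hoxa10 by at least 3.63-fold. Imprinted genes had a median of 1.46, above all matched lists, with 15 of 24 at least 2-fold higher and 1 lower: beside Dlk1, the growth factor gene Igf2 was 64.9-fold higher (147 and 9535), Sgce 13.0-fold and Plagl1 12.4-fold. Immediate-early and stress genes also had a median above all matched lists (1.49), with 8 of 15 at least 2-fold higher and 0 lower, among them Fos (129 and 2060), the stress factor gene Ddit3 (15.2-fold), Jun (8.90-fold) and Egr1 (6.73-fold).

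The remaining tissue lists had medians inside the central 95% of their matched random lists in the main setting. Neural crest markers (median 0.79, but -0.78 with the filter at the 75th percentile, and above the range at percentile 98.1 without a filter and 98.0 with a pseudocount of 1) had 4 of 10 members at least 2-fold higher and 1 lower, and held Snai2, Ednrb (at least 9.06-fold higher), Twist1 (at least 4.81-fold) and Erbb3 (3.17-fold lower). Early mesoderm markers (0.86, 2 of 8 higher, and percentile 97.7 with the filter on the control bound) held Pdgfra (at least 8.06-fold higher), Foxf1, whose 2 probe sets had opposite directions (log2 differences of 1.20 and -0.58) and which turned to -0.82 with quantile normalization, Evx1 (at least 2.38-fold higher) and Kdr (2.07-fold). Skeletal muscle markers (0.05) had a median of 1.58 with the mean over probe sets, above all matched lists, and below 0 with quantile normalization, with scaling on the hybridization controls and with probe sets of suffix a, s or x left out. They split into 3 of 7 higher, Tnni1 (at least 9.31-fold), Des (6.80-fold) and Acta1 (4.59-fold), and 2 lower, with Ttn at least 2.89-fold lower. Trophoblast markers (0.85, 3 of 7 higher and 1 lower, and percentile 98.7 without a filter) held Plac1 (4.60-fold higher), Krt7 (at least 2.26-fold), Cdx2 (at least 1.86-fold) and Tfap2c (2.74-fold lower). Epithelial markers (-0.44, but 0.02 without a filter) had 3 of 12 higher, the simple keratins Krt19 (7.17-fold), Krt8 (4.82-fold) and Krt18 (4.78-fold), and 3 lower, led by the epithelial splicing regulator Esrp1 (4.53-fold). Endothelial markers (-0.35, but 0.21 with probe sets of suffix a, s or x left out, 1 of 8 higher and 2 lower) held Flt1 (at least 3.08-fold higher), Esam (3.29-fold lower), Pecam1 (234.1 and 106.5) and Kdr. Leukocyte markers (0.72, 3 of 7 higher, and percentile 99.4 without a filter) held Tyrobp (at least 2.76-fold higher), Csf1r (4.64-fold), C1qb (at least 2.25-fold) and Laptm5 (1.94-fold lower). Other Csf1r probe sets above the filter had log2 differences of 1.08 and 0.40. Cartilage and bone markers (-0.07, but 0.07 without a filter, 0.06 with the filter on the control bound and 1.58 with the filter at the 75th percentile, 1 of 8 higher and 2 lower) had Col11a1 27.9-fold higher, Sp7 1.57-fold higher, Alpl 2.37-fold lower and Col9a1 at least 1.79-fold lower. Of 12 measured erythroid markers 3 passed the filter (-0.47, but 0.06 without it, 1 lower): Gata1 (at least 2.01-fold lower), Klf1 (at least 1.39-fold lower) and Epor (66.4 and 70.5). The cartilage and epithelial lists had means above 0 and medians below it.

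No listed gene of glycolysis or of the ribosome reached 2-fold. Most ribosomal signals lay in the bright range, where control ratios were lower. None of 15 glycolysis genes reached 2-fold in either direction (median -0.15), and the members with the largest log2 difference were Hk1 (0.65), Hk2 (0.53), Pfkp (-0.52, with probe sets of both directions) and Pfkm (0.50). None of 15 ribosomal protein genes did either (median -0.18), and the members with the largest difference were Rps6 (-0.50), Rpl8 (-0.27), Rps3 (-0.26) and Rpl7 (-0.25). Of these 15 genes, 14 measured more in undifferentiated cells than the dimmest Cre control (8340), as did 4 glycolysis genes. The mean log2 ratio of day 15 over undifferentiated was 0.27 for the bright Cre controls and 0.47 for the dimmer BioB controls. Whether bright signals were compressed or shifted as a whole was not tested, so the ribosomal differences may be understated or overstated. Of 9 housekeeping reference genes (median -0.09, mean 0.41, and a median above 0 with quantile normalization) 2 were at least 2-fold higher, the class I antigen light chain B2m (9.99-fold) and Actb (2.12-fold), while Gusb measured 0.75 and the X-linked Hprt -0.67. WNT, BMP and NOTCH target genes had a median of 0.25, which scaling on the hybridization controls brought below 0 and the mean over probe sets brought to 0.76, above all matched lists, with 3 of 18 at least 2-fold higher and 2 lower: Bambi at 2.64, Smad6 at 1.57, Id1 at -1.70 and Sp5 at -1.34.

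**Figure D1:**
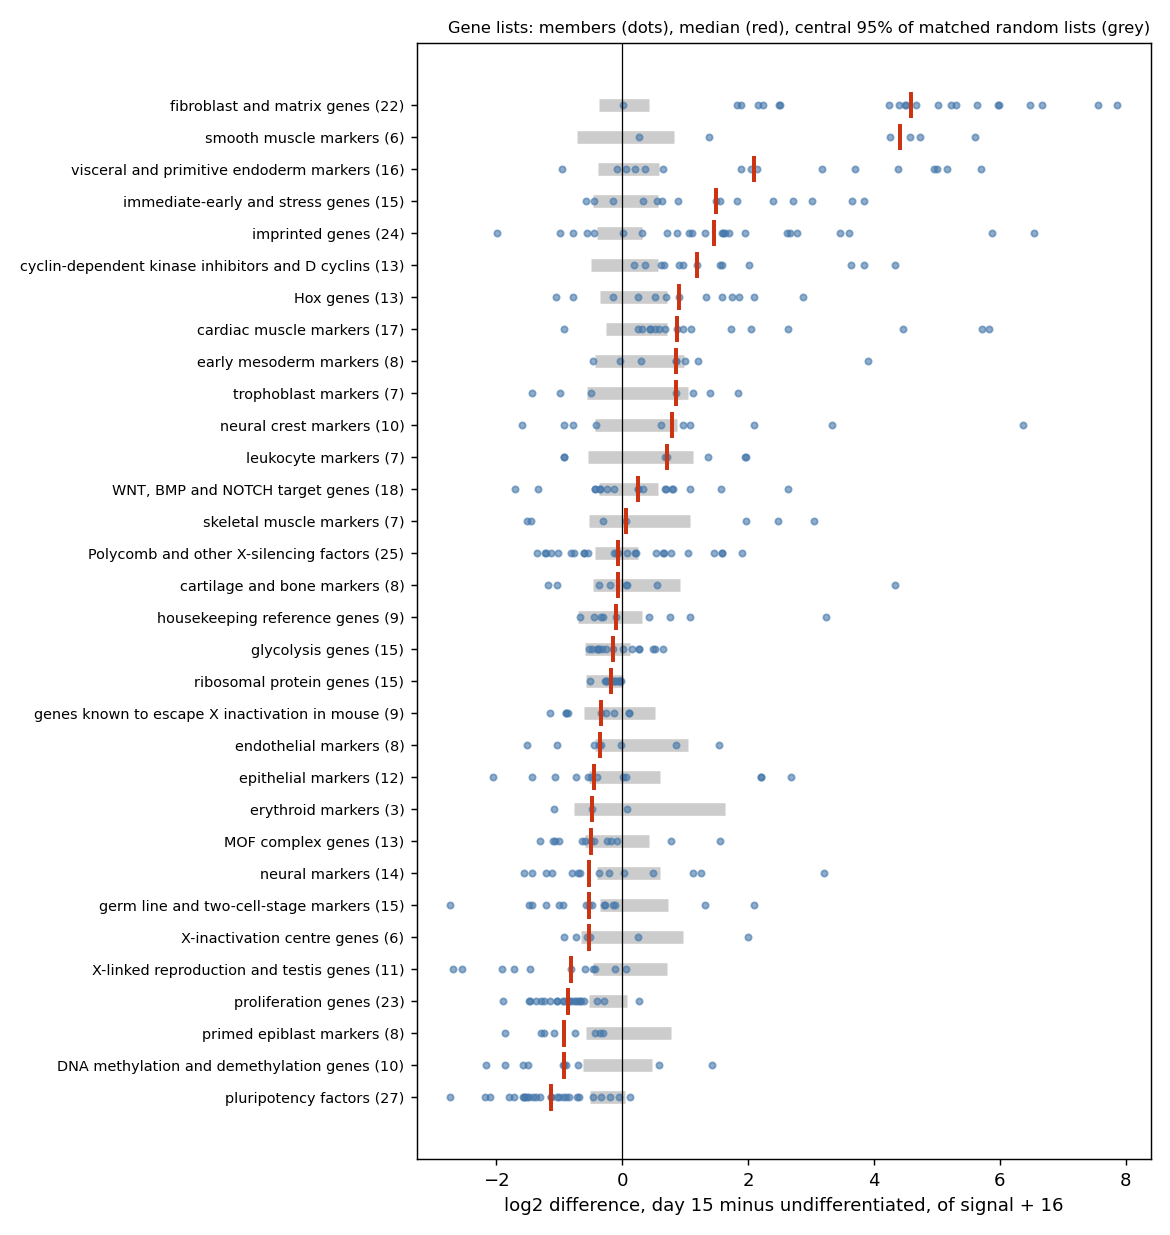
Log2 difference of signal + 16, day 15 minus undifferentiated (horizontal axis), for the members above the expression filter (blue dots) of each of 32 gene lists, with the number of such members in brackets, the list median (red bar) and the central 95% of medians of 10000 expression-matched random lists (grey). Fibroblast and matrix genes (median 4.59) lie farthest to the right and pluripotency factors (median -1.13) farthest to the left.

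X-linked genes were lower relative to autosomal genes at day 15. The median log2 difference was -0.18 over 418 X-linked genes (95% interval over genes -0.28 to -0.11) and 0.0064 over 11524 autosomal genes (-0.014 to 0.027), a difference of -0.19. At least 2-fold lower were 14.4% of X-linked genes (60 genes, interval 11.1% to 18.1%) against 8.21% of autosomal genes (7.71% to 8.73%). At least 2-fold higher were 12.7% (53 genes, 9.64% to 16.3%) against 16.7% of autosomal genes. The X-linked median lay at percentile 0.06 of autosomal lists matched on mean expression, whose central range was -0.12 to 0.05. The X-linked minus autosomal median log2 change was -0.094 without the expression filter and -0.090 among genes within 2-fold. The X-linked genes at least 2-fold lower at day 15 were 28.0% (autosomal 19.8%) with scaling on the hybridization controls and 10.9% (autosomal 5.52%) with a pseudocount of 64.

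Among genes above the filter, the difference was of like size at each level of expression. It was -0.20 in the lowest of 3 bins of mean expression (124 X-linked genes, percentile 0.63), -0.22 in the middle bin (111 genes, percentile 1.21) and -0.21 in the highest bin (183 genes, percentile 0.03). In 8 of 9 consecutive 20 Mb windows the X-linked median lay below the autosomal median. The window nearest the centromere had the largest difference (-0.41, 55 genes, percentile 0.12), the window that holds Xist had -0.11 (53 genes, percentile 28.7), and the third window had 0.05 (48 genes). The first window alone lay outside the central 95% of matched lists, and the other 8 lay inside it at percentiles 5.52 to 62.9. Without the first window the X-linked difference was -0.14.

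Whole autosomes also differed from each other in this pair of arrays. Of 19 autosomes, 11 had medians outside the central 95% of matched lists, 5 below and 6 above. Against the median of the other autosomes, the X had the lowest value of all chromosomes (-0.19), followed by chromosome 17 (-0.13), while chromosome 12 had the highest (0.17). Against expression-matched lists, chromosome 17 lay as low (-0.14) as the X (-0.14), and chromosome 12 lay 0.20 above.

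**Figure D2:**
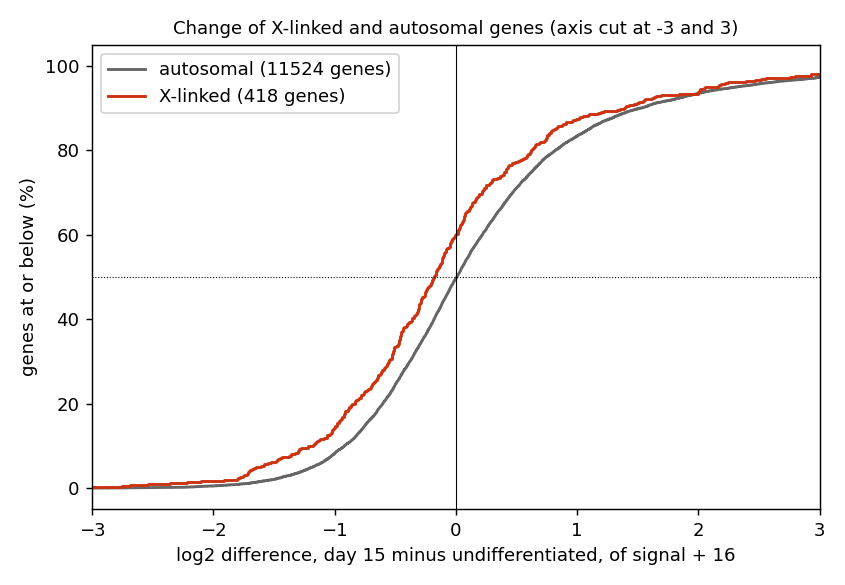
Cumulative share of genes in percent (vertical axis) against the log2 difference of signal + 16, day 15 minus undifferentiated (horizontal axis, drawn from -3 to 3), for 418 X-linked genes (red) and 11524 autosomal genes (grey). The X-linked curve crosses 50% at -0.18 and the autosomal curve at 0.0064.

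**Figure D3:**
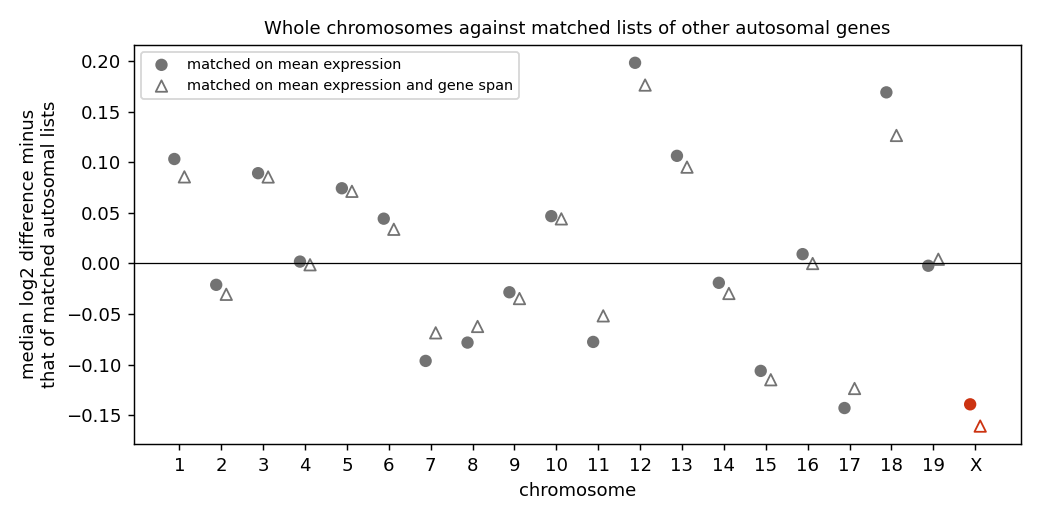
Median log2 difference of each chromosome minus the median of random lists of other autosomal genes (vertical axis), matched on mean expression (filled circles) or on mean expression and gene span (open triangles); the X is red. Matched on expression the X (-0.14) and chromosome 17 (-0.14) are the lowest, and chromosome 12 (0.20) is the highest.

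Xist, the noncoding RNA that coats the inactive X, was higher at day 15. The brightest of its 3 probe sets, the one that represents the gene, read 550 in undifferentiated cells and 2242 at day 15 (4.07-fold). The other two lay below the filter and read 1.40 and 85.3, and 2.40 and 39.7. Its antisense transcript Tsix measured 75.4 and 32.1 (at least 2.12-fold lower), a log2 difference of -0.93 that fell short of the 2-fold call. The other 4 genes of the X-inactivation centre above the filter had log2 differences of -0.73 (Chic1), -0.55 (Nap1l2), -0.51 (Rlim, with probe sets of both directions) and 0.25 (Ftx, below 0 with quantile normalization and with scaling on the hybridization controls). The list median was -0.53 (percentile 5.90, and -0.64 at percentile 0.4 without a filter). Jpx, Cdx4, Tsx and Zcchc13 enter only without a filter and lay below 35.6 on both arrays.

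Genes known to escape X inactivation in mouse were not higher as a group. Of 9 above the filter, 1 was at least 2-fold lower and 0 at least 2-fold higher, with a median of -0.34 (percentile 16.5). The noncoding gene 5530601H04Rik was 2.45-fold lower, the histone demethylase gene Kdm6a 1.87-fold, Pbdc1 1.86-fold, the translation factor gene Eif2s3x 1.81-fold and the RNA helicase gene Ddx3x 1.27-fold. Values nearer 0 were those of 1810030O07Rik (-0.25), Mid1 (-0.13), Kdm5c (0.11, with probe sets of both directions) and Shroom4 (0.11), and those of Kdm5c and Shroom4 lay below 0 with quantile normalization and with scaling on the hybridization controls. Another Mid1 probe set above the filter read 152.1 and 68.9, a log2 difference of -0.99. Car5b lay below the filter (22.2 and 50.6).

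Among single X-linked genes, the largest gains after Col4a5 were of the matrix proteoglycan gene Bgn (27.4-fold), Asb12 (at least 8.12-fold), the heparan sulfate sulfotransferase gene Hs6st2 (13.7-fold) and the glutamate receptor gene Gria3 (at least 5.04-fold). Capn6 (15.4-fold), Sh3bgrl (10.7-fold) and Arhgap6 (at least 12.5-fold) followed. The largest losses after Glod5 and Slc38a5 were of the homeobox genes Rhox9 (8.29-fold) and Rhox6 (7.23-fold), Pdzd4 (5.49-fold), Efhc2 (at least 5.67-fold), the stem cell Ras gene Eras (4.36-fold) and Mageb16 (3.82-fold). X-linked reproduction and testis genes had 5 of 11 members at least 2-fold lower and 0 higher (median -0.81, percentile 0.015), with Rhox5 3.33-fold lower.

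Genes that write or read silent chromatin were found on both sides. Polycomb and other X-silencing factors had 5 of 25 members at least 2-fold higher and 5 at least 2-fold lower (median -0.06, mean 0.05, percentile 62.1). The 4 with the largest difference were Ciz1, which anchors Xist RNA in the nucleus (1.90), the macroH2A gene Macroh2a2 (1.59), Pcgf5 (1.59) and Bmi1 (1.46). The 5 lower members, named after their values were seen, were Cbx7 (-1.35), Eed (-1.22), Jarid2 (-1.21), Ash2l (-1.13) and Ezh2 (-1.02). Genes of the MOF histone acetyltransferase complexes had a median of -0.49 (percentile 7.17), with 1 of 13 at least 2-fold higher, Msl3 (1.56), and 3 lower, Hcfc1 (-1.30), Wdr5 (-1.09) and Msl2 (-1.06). Other Msl2 probe sets above the filter had log2 differences of -0.31 and -0.16.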

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

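The tests in this part were chosen after the results were seen. Signals outside the gene comparisons differed between the arrays. The 6 probe sets for the Bacillus subtilis Lys control read 5124 to 11560 on the day 15 array and 0.4 to 15.3 on the undifferentiated array, and the 6 for the Dap control read 4157.8 to 15243 on the undifferentiated array and 0.4 to 18.1 at day 15. Of 2255 probe sets above the filter that do not name a single gene, 213 were at least 2-fold higher at day 15 and 162 at least 2-fold lower.

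X-linked genes were lower at day 15 than autosomal genes by a median of -0.19 on the log2 scale. The X-linked median minus that of autosomal lists matched on both expression level and gene span was still -0.16, outside their central 95%. With this matching 10 of 19 autosomes also lay outside their range. Lying outside it therefore does not decide whether expression level and gene span are the whole cause. Differences between whole chromosomes stay open: 1 autosome of 19 lay as far below lists matched on expression as the X, and 0 did so once span was matched too. Silencing of an X, which the labels report from RNA FISH, and loss of an X from part of the culture cannot be told apart here, because the median of the escape genes minus that of the other X-linked genes was -0.16, with an interval from -0.89 to 0.11 around their median of -0.34. A lower X-linked output through inactivation may contribute, and a single pair of arrays leaves it as a hypothesis.

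Pluripotency transcripts kept a median of 45.8% of their undifferentiated level at day 15. If unchanged stem cells were the only source, every other abundant transcript of these cells would keep at least that share. Among 1291 genes outside the list with over 1 probe set as bright as the list (494.8 or more in undifferentiated cells), 17 had all such probe sets more than 1 SD (0.28) below its lower limit of 42.1%. Resampled probe set deviations gave a median of 1, with the central 95% reaching 4, so for these bright probe sets such deviations alone fall short of 17. They leave out variation between cultures, so the count does not exclude unchanged stem cells as the only source. Rasgrp2 read 1263 and 152, and Gab1, with 3 such probe sets, kept 26.1%. Over 3 limits of the share, with and without the margin of 1 SD, the count passed chance in 6 of 6 settings, but in 1 of 6 once dimmer probe sets, whose spread is wider, were added. The SD of the 27 factors was 0.67, above the 0.20 to 0.39 of deviations of equally bright probe sets, but within the 0.33 to 0.79 of all probe sets above the filter. A partial decline within cells, or a smaller share of unchanged cells beside others that kept these transcripts, also stays open. Dppa3, with 15.1% of its level on the log2(signal + 16) scale, was the lowest member.

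Fibroblast and matrix genes were higher at day 15 by a median of 4.59. Feeder fibroblasts, which the protocol removes before differentiation, make the same transcripts, so for this list carried-over or regrown feeders cannot be told apart from fibroblasts formed in the embryoid bodies. Of the 27 cardiac and endoderm markers that are no matrix genes, 12 were at least 2-fold higher and 0 lower. Their median of 0.88 lay above the central 95% of matched lists (-0.18 to 0.61). Both lists they come from had already lain above their ranges, so this outcome is no separate support. Feeders were not measured alone, so these markers do not decide whether feeders contributed to the lineage profile.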

How the results depend on the processing

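Scaling on the 18 hybridization controls, the filter on the control bound, leaving out the first X window and matching on gene span were chosen after the data were seen. The X-linked minus autosomal median log2 change was negative under all alternatives run, from -0.24 with means in place of medians to -0.094 without the expression filter and -0.090 with genes past 2-fold left out. The cause was not tested for the filter, and leaving out large differences shortens both distributions by construction. Leaving out each autosome in turn gave -0.20 to -0.18, and leaving out each X window in turn -0.22 to -0.14. The genes at least 2-fold higher at day 15 numbered 907 with a filter at the 75th percentile, by construction from fewer genes, 3131 at 1.5-fold and 782 at 4-fold. The genes at least 2-fold lower at day 15 numbered 2397 with scaling on the hybridization controls, which shifts all genes by -0.39, 2512 at 1.5-fold and 68 at 4-fold. X-linked genes at least 2-fold higher at day 15 became 21.3% at 1.5-fold and 6.22% at 4-fold. X-linked genes at least 2-fold lower at day 15 became 28.7% at 1.5-fold and 1.67% at 4-fold, 28.0% with scaling on the hybridization controls and 10.9% with a pseudocount of 64, which damps dim genes. Foxf1 was reversed with quantile normalization (gene: Foxf1, -0.82). Its probe sets above the filter already had opposite directions on the deposited scaling (1.20 and -0.58). Whether the probe set that represents the gene changed was not checked, and the cause was not tested. Of 163 single genes, the log2 difference moved by more than the probe set SD of 0.53 for 48 with the mean over probe sets, 56 with a pseudocount of 64 and 32 with a pseudocount of 1, which damp or stretch dim genes by construction, and for 18 with probe sets of suffix a, s or x left out. Of 32 lists, 11 to 18 had medians outside their matched range, with 24 lists left to measure at the 75th percentile filter. Of the 15 lists outside their range in the main setting, 4 lay inside it under at least 1 alternative (neural, germ line, primed epiblast and DNA methylation), and 0 changed sign among the alternatives run. Of the 17 inside it, 7 lay outside under at least 1 alternative and 8 had a median of the opposite sign under at least 1, as given beside each list. No paired analysis was possible because each condition has 1 array, and for the same reason no array could be left out. Dim signals are limited by the control bound of 35.6, and the values without a filter include genes below it on both arrays.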

Other observations

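The tests in this part were chosen after the data were seen. Genes sharing a symbol stem were grouped where at least 8 passed the filter, which gave 189 families, of which 21 had medians below the central 95% of 2000 matched random lists and 14 above; chance alone would put about 5% outside. The 9 exosome subunit genes (Exosc) had a median log2 difference of -1.03 with 5 at least 2-fold lower, led by Exosc5 (1345 and 554) and Exosc2. The families Nop (8 genes, -0.95), Nol (9 genes, -0.94), Rrp (8 genes, -0.94) and Utp (11 genes, -0.90) lay beside the Mcm stem (10 genes, -0.98). Most Nop, Nol, Rrp and Utp genes act in ribosomal RNA maturation. Utp15 was 3.27-fold lower (1305 and 399). The Nol stem also held Nol4l, at least 2-fold higher (54.7 and 144), and the Mcm stem also held Mcm3ap (1295 and 623). The other families below their range were Nup (-0.76), Fgf, Naa, Tex, Prpf, Rad, Polr, Parp, Prdm, Ddx, Dhx, Snhg, Mrpl, Cep and Zfp (-0.06).

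Of 8 annexin genes, which encode calcium-dependent membrane-binding proteins, 7 were at least 2-fold higher (median 2.86), with Anxa1 23.1-fold and Anxa2 19.5-fold higher, while Anxa7 had signals of 1777 and 1570. Of 27 collagen-stem genes 19 were higher and 1 lower (median 2.73), of 11 ADAMTS metalloproteases 7 (median 2.25, Adamts5 at least 20.2-fold), of 8 intracellular serpins 6 (median 2.61, Serpinb6b at least 14.2-fold and Serpinb9 at least 14.8-fold), and of 9 carbohydrate sulfotransferases 5 (median 1.24, Chst11 20.8-fold). The other families above their range were Adam (1.17), Cdkn (1.11), Man (1.10), Stx (0.85), Rap (0.75), Hspa (0.71), Arhgap (0.52), Sec (0.31) and Tmem (0.25), of which Sec and Tmem turn below 0 with scaling on the hybridization controls. Probe sets of the Serpinb6 and Serpinb9 paralogs were not checked for shared sequence.

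Long genes were higher at day 15 relative to short genes. The decile of genes with the longest genomic span (median 189 kb) had a median log2 difference of 0.39 (0.32 to 0.46 over genes), with 31.2% at least 2-fold higher and 4.85% lower. The next decile had 0.19, the 8th 0.03, and the 7 shortest had medians from -0.12 to -0.05. Over genes, which are not independent replicates, Spearman's rho of span and log2 difference was 0.12, 0.13 without any gene of the 32 lists, and 0.11 after removing the median of each decile of mean expression. Scaling on the hybridization controls, which shifts all genes by -0.39, would bring the median of the longest decile to about 0 and leave its distance to the other deciles as it is.

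The lowest stretch of 6 neighbouring measured genes in the genome lay on the X and held Timm17b, Pcsk1n, Eras, Hdac6, Gata1 and Glod5, with a median of -1.64; 16 of 1000 shuffles of gene order gave a stretch as low anywhere. Beside Glod5 and Eras, Hdac6 was 3.56-fold lower, Pcsk1n 2.95-fold, Gata1 at least 2.01-fold and Timm17b 1.16-fold. The second lowest separate stretch was also X-linked and held Rhox5, Rhox6 and Rhox9 (median -1.35), but 303 of 1000 shuffles gave a stretch as low. The highest, on chromosome 5 around Sema3a, Sema3e, Cacna2d1 and Sema3c (median 2.76), was matched in 312 shuffles.

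The 3′ to 5′ signal ratio of the Actb control probe sets was 2.34 on the undifferentiated array and 1.72 at day 15, and that of Gapdh was 0.82 on both.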
